A study of Mus musculus with 18 samples.

How the data were processed

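RNA was extracted with Trizol from mouse esophageal organoids and sequenced as bulk RNA-seq, per the labels' protocols. The authors deposited 3 comparison tables of 24421 genes each, which hold whole-number counts per gene for every sample, the authors' normalized values per sample and the authors' log2 fold changes, p-values and adjusted p-values, per the file headers. Per the submitters' processing notes, STAR 2.6.0a, DESeq2 1.26.0 and the mm10 build were used. The counting program, its strand setting and the annotation used for counting are not given in the sources used here. The deposited log2 fold change and adjusted p-value columns were read for the number of genes past the threshold and their overlap with the calls made here. The 18 deposited normalized columns were not used. Of the gene symbols, 24394 are shared by the tables and 23376 (95.7%) were found in GENCODE M21 (GRCm38), which gave gene positions, lengths and GC content. The tumor and PB tables hold 27 symbols turned into dates, which were left under the names deposited.

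Samples were grouped by title, genotype and treatment in the labels. Each deposited count column was analysed with R 4.3.3 and edgeR 4.0.16: genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and groups were compared with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each comparison was fitted within its own table. The difference of the sgTgfbr2 effect between stages was fitted on the 12 premalignant and tumor libraries as a contrast, in which an additive difference between the tables cancels. The line contrast used 1 mean per line with the sgScr libraries. Normalized CPM are counts scaled to a common total, relative to the TMM-scaled library. CPM of the library total are given for Tgfbr2, for marker sums, for genes named as part of such a sum, and where so named. The standard error of a log2 fold change is its size over the square root of the test's F.

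The gene lists, the tests, the grouping and the rule for named genes were set before the data were examined. Per comparison the rule took Tgfbr2, Smad3, Trp53, Cdkn2a and Myc. It added the 8 highest and 8 lowest log2 fold changes among other genes past the threshold with a mean of at least 5 CPM and all samples of one group above all of the other, leaving out predicted or unnamed genes. It also took up to 4 members past the threshold, by smallest p, of each list with a fry adjusted p under 0.05 or with 3 or more members past the threshold. The stage and line contrasts took 5 genes at each end. Multigene family members are named as uncertain in their counts, and some genes that the rule took are not reported here. Of 37 gene lists, those with at least 3 measured members (31, 36 and 32 in the premalignant, tumor and PB comparisons) were tested by fry (limma 3.58.1), which tests whether a list's genes move, on balance, one way and compares the list with no other genes. They were tested again by camera, which compares a list with the other genes, with a preset correlation of 0.01 and with an estimated one. A p-value given with an estimated or a preset correlation is camera's. Genes without a count in a group were given a lower bound on the fold, from 3 counts over the group. Genes with 1 to 3 counts were given a ratio with a 95% counting interval.

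Replicates were compared before averaging, by chi-square over genes with at least 20 counts in a pair. The statistic per degree of freedom was 6.48 to 21.3 in premalignant sgScr, 6.42 to 7.10 within and 38.1 to 57.7 between the sgTgfbr2 lines, 9.91 to 17.3 in tumor sgScr, 17.9 in tumor sgTgfbr2, 1.79 to 2.03 in vehicle and 1.51 to 1.65 in PB, so no libraries were merged. With 14993749 to 21784140 counts per library, 3 counts stand for 0.138 to 0.200 CPM. On simulated counts, 2-fold changes were recovered for 82% of genes in the premalignant comparison, 73% in the tumor comparison, 99% under PB, 55% in the stage contrast and 88% in the line contrast, and 4-fold changes for 96%, 96%, 100%, 94% and 100%. The share of false calls was 3.78%, 2.31%, 6.13%, 9.15% and 6.93%, so it lay above 5% in 3 of the 5. The simulation changed 100 genes at each fold, drew each library independently and gave the libraries of a line no shared effect. Far more genes passed in the data, so these shares need not describe the error of the real comparisons. Alternatives were DESeq2 1.42.0 (size factors and Wald test), limma-voom, no filter and a filter of 1 CPM, a minimum absolute log2 fold change of 1 (for the calls and for the tumor gene sets followed under PB), a replicate block, each replicate left out in turn, and the line settings.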

Results

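RNA-seq counts of 18 libraries declared as mouse esophageal organoids were compared. Organoids are three-dimensional cultures grown from dissociated tissue in a basement membrane gel. All were declared to lack Trp53, to overexpress Myc and to carry a guide against Cdkn2a, with a control guide (sgScr) or a guide against Tgfbr2 (sgTgfbr2), which encodes the type II receptor of TGF-beta. The groups were premalignant sgScr (n = 3), premalignant sgTgfbr2 (n = 4, from 2 numbered lines), tumor sgScr (n = 3), tumor sgTgfbr2 (n = 2), and tumor sgTgfbr2 organoids given vehicle (n = 3) or 2 µM pinaverium bromide (PB, n = 3), a calcium channel blocker, after 72 h of culture. The organoid medium of all 18 libraries was listed with 2 µM A83-01, an inhibitor of the TGF-beta type I receptor. Each library held 14993749 to 21784140 counts over 15565 to 16713 detected genes. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

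Tgfbr2 transcripts were lower with the Tgfbr2 guide at both stages and were still present. In premalignant organoids the level was 195 ± 20.8 CPM (counts scaled to a common library total; SD, n = 3) in sgScr, with single libraries at 188, 179 and 219. In sgTgfbr2 it was 113 ± 21.2 (SD, n = 4), at 128, 131, 105 and 86.2. In the tumor libraries it was 120.3 ± 8.76 (SD, n = 3; 120.2, 112 and 129) against 69.3 ± 2.64 (SD, n = 2; 67.5 and 71.2). The vehicle libraries held 93.1, 94.4 and 103 CPM, and the PB libraries 69.4, 68.6 and 66.8. The log2 fold changes by edgeR were -0.86 ± 0.14 (SE, adjusted p = 0.00132) in premalignant and -1.08 ± 0.13 (adjusted p = 4.19e-07) in tumor libraries. RNA of other cell types also differed between the tumor groups. A list of muscle marker genes summed to 14596 CPM in tumor sgScr and 1801 in tumor sgTgfbr2. How much of the tumor difference in Tgfbr2 comes from the guide was therefore not tested. Tgfbr2 lies on chromosome 9 of GRCm38 at 116084293 to 116175360, minus strand. The labels do not give the guide's target site, and a frameshift need not change a transcript's count.

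**Figure D1:**
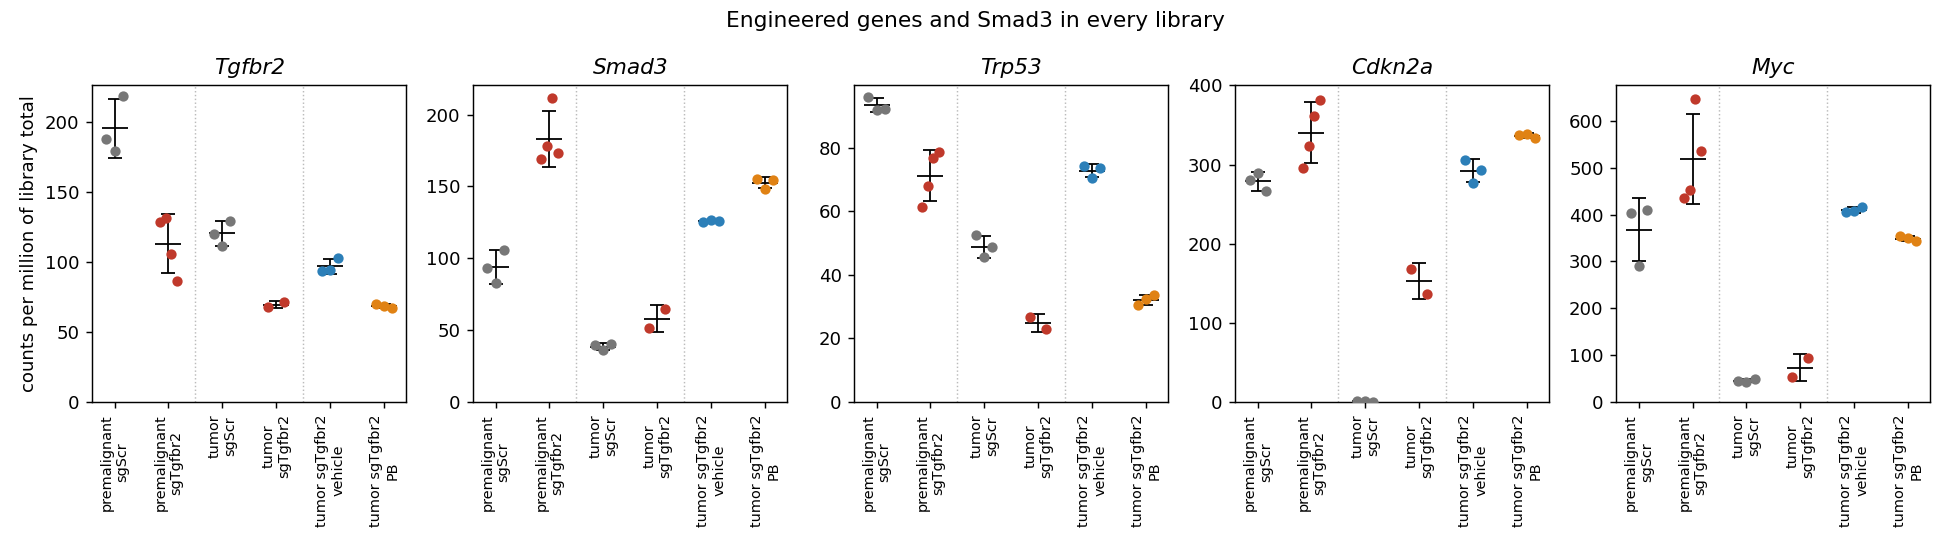
CPM of the library total (vertical axis) of Tgfbr2, Smad3, Trp53, Cdkn2a and Myc, with points for libraries and bars for the mean and SD of each group; dotted lines part the 3 separately deposited tables. Mean Myc was 44.7 in tumor sgScr and 72.5 in tumor sgTgfbr2, and between 349 and 518 in the other 4 groups.

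Smad3, the TGF-beta signal transducer encoded on chromosome 9 at 63646767 to 63757994, was higher in premalignant sgTgfbr2 than in sgScr, at 179 ± 18.2 against 96.1 ± 9.60 normalized CPM (SD; log2 fold change 0.90 ± 0.11, edgeR adjusted p = 3.54e-04). Trp53 was lower (log2 fold change -0.46 ± 0.10, adjusted p = 0.00539) and its transcripts were counted in each of the 18 libraries, all declared Trp53-null. Cdkn2a (0.22 ± 0.11, adjusted p = 0.124) and Myc (0.43 ± 0.16, adjusted p = 0.0515) did not pass the threshold in that comparison, and both passed with line 2 alone (log2 fold changes 0.34 and 0.62).

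The premalignant comparison asks what loss of Tgfbr2 changes before tumors form. The 16 genes named next passed an adjusted p of 0.05 by edgeR with all libraries of the groups apart. Lcn2, an iron-binding acute-phase protein, stood at 205 ± 179.9 normalized CPM in sgTgfbr2 and 3.02 ± 2.19 in sgScr (SD; log2 fold change 6.08 ± 0.99, SE). Ltbp2, a matrix protein of the latent TGF-beta binding family, rose by 5.45 ± 0.49, Nos2, the inducible nitric oxide synthase, by 4.88 ± 0.80, and Steap4, a metalloreductase, by 5.17 ± 0.92. Lypd2 (6.71 ± 1.47), Mtus2 (5.88 ± 1.38), Sprr2d (4.46 ± 1.02) and Spn (4.28 ± 0.56) completed the 8 highest; Sprr2d belongs to a multigene family, so its counts are uncertain. The lowest were Krt13, a keratin of suprabasal esophageal cells, at 13.4 ± 8.92 against 139 ± 16.8 CPM (log2 fold change -3.38 ± 0.44), Gsta1 (-3.19 ± 0.15; a family with near-identical copies, counts uncertain), the EGF-family ligand Epgn (-3.16 ± 0.16), Cntn1 (-2.45 ± 0.20), Tbx2 (-2.44 ± 0.47), Krt16 (-2.24 ± 0.14), Teddm3 (-2.22 ± 0.15) and Cd5 (-2.03 ± 0.52). The 2 sgTgfbr2 lines stood apart in the 8 highest genes, all lower in line 2 than in line 1 by edgeR, so that the pooled folds lie between those of the lines. Mean CPM in lines 1 and 2 were 357 and 51.4 for Lcn2, 125 and 17.2 for Steap4 and 65.9 and 12.6 for Nos2. With line 1 or line 2 alone against sgScr, an alternative set beforehand, the log2 fold changes were 6.92 and 4.09 for Lcn2, 6.01 and 3.12 for Steap4, 5.66 and 3.24 for Nos2, 5.99 and 4.66 for Ltbp2, 4.93 and 3.19 for Spn, 7.64 and 3.76 for Lypd2, 6.82 and 2.74 for Mtus2 and 5.37 and 1.90 for Sprr2d. Of the lowest, Krt13 (-4.53 and -2.74), Tbx2 (-3.79 and -1.76) and Cd5 (-3.58 and -1.31) were lower by more in line 1. All 16 genes kept their direction and passed the threshold in each line. The rule that chose them required the libraries of both lines to lie apart from sgScr. Their direction was therefore fixed in advance, and the single-line fits are no independent check.

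Among genes known as TGF-beta and SMAD targets, 13 rose and 1 fell of 26 measured (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.47 (fry adjusted p = 0.00455, adjusted p = 0.404 with an estimated correlation). They included Ctgf (2.41 ± 0.22), Cdkn2b (0.93 ± 0.09) and Itgb6 (0.95 ± 0.11). By edgeR against sgScr, line 1 had 13 higher and 6 lower of the list's 26 genes, and line 2 had 17 and 2. The receptor partner Tgfbr1 (1.05 ± 0.10) and the ligand Tgfb1 (0.69 ± 0.09) were also higher. Among BMP and ID targets, 5 rose and 0 fell of 10 measured (5 and 0 adjusted over the list alone) (fry adjusted p = 0.00243, adjusted p = 0.241 with an estimated correlation). Id1 stood at 228 ± 17.3 against 23.5 ± 2.91 CPM (log2 fold change 3.28 ± 0.12), with Id2 (1.58 ± 0.09) and Id3 (2.08 ± 0.18). The list's median against sgScr was 0.07 in line 1, with 5 higher and 3 lower of 11 genes by edgeR. It was 1.08 in line 2, with 6 and 0. The list medians and list counts of single lines in the report were chosen after seeing the data. These transcripts were measured with the TGF-beta type I receptor inhibitor A83-01 listed at 2 µM in the organoid medium.

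Lists of signalling and inflammatory genes rose by the same test. Of the MAPK feedback and immediate early genes, 14 rose and 1 fell of 22 measured (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.60 (fry adjusted p = 7.61e-04, adjusted p = 0.241 with an estimated correlation). Egr1 rose by 1.51 ± 0.10 and Dusp4 by 1.62 ± 0.11 (log2). Of the NF-kB and inflammatory genes, 17 rose and 1 fell of 23 measured (17 and 1 adjusted over the list alone), with a median log2 fold change of 0.93 (fry adjusted p = 0.0314, adjusted p = 0.431 with an estimated correlation). Members included Il1a (2.54 ± 0.28), Icam1 (1.22 ± 0.12) and Nfkbia (0.93 ± 0.10). The list's median differed between the lines, at 1.36 against sgScr in line 1, with 21 higher and 1 lower of 24 genes by edgeR, and 0.73 in line 2, with 16 and 3. Beside the NF-kB genes, of the immune marker genes, 2 rose and 0 fell of 3 measured (2 and 0 adjusted over the list alone), with a median log2 fold change of 1.12 (fry adjusted p = 0.00756, adjusted p = 0.404 with an estimated correlation). The list summed to 52.0 ± 13.5 against 23.3 ± 6.99 CPM, of which Cd68 made up 42.8 ± 12.9 and 18.9 ± 6.34. Cd74 rose by 1.81 ± 0.32, and Lyz2 and Tyrobp, named after their values were seen, had no count in either group. The list's median was 0.68 in line 1 and 1.45 in line 2. Of the YAP/TAZ targets, 15 rose and 1 fell of 20 measured (15 and 1 adjusted over the list alone) (fry adjusted p = 0.00315, adjusted p = 0.337 with an estimated correlation). Members included Ptpn14 (1.61 ± 0.13) and Cyr61 (1.41 ± 0.12). Of the epithelial junction genes, 13 rose and 2 fell of 23 measured (13 and 2 adjusted over the list alone), with a median log2 fold change of 0.41 (fry adjusted p = 3.02e-04, adjusted p = 0.121 with an estimated correlation). Members included the claudins Cldn3 (3.31 ± 0.30) and Cldn4 (2.05 ± 0.15) and the tight junction protein Tjp3 (2.68 ± 0.15). Of the calcium channel and handling genes, 13 rose and 1 fell of 27 measured (13 and 1 adjusted over the list alone), with a median log2 fold change of 0.55 (fry adjusted p = 0.00455, adjusted p = 0.396 with an estimated correlation). Members included the plasma membrane pump Atp2b4 (2.69 ± 0.32) and the channel subunit Cacnb1 (2.28 ± 0.41).

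Lists of growth and biosynthesis genes fell by the fry test. Of the MYC target and ribosome biogenesis genes, 0 rose and 25 fell of 26 measured (0 and 25 adjusted over the list alone), with a median log2 fold change of -0.99 (fry adjusted p = 0.00315, adjusted p = 0.337 with an estimated correlation). Ornithine decarboxylase Odc1 (-1.44 ± 0.14), Srm (-1.23 ± 0.11) and Nop58 (-1.23 ± 0.12) fell. Of the proliferation genes, 2 rose and 17 fell of 35 measured (3 and 17 adjusted over the list alone), with a median log2 fold change of -0.35 (fry adjusted p = 0.00731, adjusted p = 0.404 with an estimated correlation). The replication helicase gene Mcm5 fell (log2 fold change -1.02 ± 0.08) and Cenpf rose (0.93 ± 0.10). Of the cholesterol synthesis genes, 2 rose and 15 fell of 25 measured (2 and 17 adjusted over the list alone), with a median log2 fold change of -0.36 (fry adjusted p = 5.42e-04, adjusted p = 0.241 with an estimated correlation). Members included Acat2 (-1.34 ± 0.09) and Idi1 (-1.22 ± 0.11). Of the integrated stress response genes, 0 rose and 12 fell of 22 measured (0 and 12 adjusted over the list alone), with a median log2 fold change of -0.39 (fry adjusted p = 0.00455, adjusted p = 0.396 with an estimated correlation). Members included Atf5 (-1.67 ± 0.21) and Shmt2 (-0.80 ± 0.08), and the list's median was -0.45 in line 1 and -0.81 in line 2. Of the stress and wound keratins, 0 rose and 4 fell of 4 measured (0 and 4 adjusted over the list alone), with a median log2 fold change of -1.85 (fry adjusted p = 3.02e-04, adjusted p = 0.121 with an estimated correlation). Krt6a stood at 731 ± 129 against 2482 ± 145 CPM.

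By edgeR's quasi-likelihood test, 6057 of 13098 genes passed a Benjamini-Hochberg adjusted p of 0.05, 2979 higher and 3078 lower. This fit treats the libraries of an sgTgfbr2 line as independent. Their chi-square per degree of freedom was 6.42 to 7.10 within lines and 38.1 to 57.7 between lines. The p-values of the premalignant genes and lists may therefore be too small. The authors' deposited table holds 6354 genes past the same threshold. With an absolute log2 fold change of at least 1 the balance was uneven, at 1102 higher and 437 lower genes. No list call of this comparison held with an estimated correlation (smallest adjusted p = 0.121), and leaving out premalignant sgScr replicate 1 or 2 lowered the number of higher genes to 1977 or 1954. Leaving out sgScr replicate 3 gave 2705. By chi-square per degree of freedom, replicate 3 lay further from replicates 1 and 2 (12.2 and 21.3) than these from each other (6.48). Whether this accounts for the lower counts was not tested.

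The tumor comparison sets libraries labelled tumor sgScr and tumor sgTgfbr2 side by side, with the same declared genotypes as the premalignant ones. In CPM of the library total, mean Myc was 44.7 and 72.5 in them against 349 to 518 in the other 4 groups, and mean Cdkn2a 0.547 and 152 against 279 to 340.4, where all 6 groups were declared to overexpress Myc and to carry the Cdkn2a guide. The libraries labelled tumor sgTgfbr2 held transcripts known from gastric glands. Pgc, which encodes the pepsinogen progastricsin, stood at 22787 ± 2584 normalized CPM (SD, n = 2) against 0.0342 ± 0.0592 (SD, n = 3). With 2 counts in tumor sgScr, its ratio was 602579-fold (counting interval 166811 to 4975690) in TMM-scaled counts. The gastrokine Gkn1 stood at 1272 ± 112 CPM with no count in tumor sgScr, at least 22418-fold higher against a floor of 3 counts over the group. By the same floor Gkn2 was at least 17364-fold, Gif, the gastric intrinsic factor, 11532-fold, Dpcr1 9518-fold and the trefoil peptide Tff2 5752-fold higher. Colipase Clps (5497 ± 829 CPM) and the phospholipase Pla2g1b (2326 ± 485 CPM), both known from the pancreas, had 2 counts and 1 count in tumor sgScr, with ratios of 145360-fold (counting interval 40239.7 to 1200280) and 122992-fold (counting interval 22075 to 4857920). Such floors and intervals cover counting error only.

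The libraries labelled tumor sgScr held cornified squamous and skeletal muscle transcripts. Serpinb3c stood at 2855 ± 317 CPM with no count in tumor sgTgfbr2 (at least 38914-fold lower), the fast troponin Tnnc2 at 1277 ± 137 CPM and the myosin heavy chain Myh8 at 1096 ± 50.5 CPM. Lce3f (2396 ± 178 CPM), Lce3a, Lce3b, Lce3c and Lce3e of the late cornified envelope family were also without a count in tumor sgTgfbr2; as members of a multigene family, like Serpinb3c and the myosins, their separate counts are uncertain. Skeletal actin Acta1 made up 8803 ± 149.8 CPM in tumor sgScr and 0.486 ± 0.687 in tumor sgTgfbr2, where 20 counts were found. Of the squamous differentiation genes, 5 rose and 21 fell of 26 measured (5 and 21 adjusted over the list alone) (fry adjusted p = 2.57e-04, adjusted p = 0.157 with an estimated correlation). Sprr3 stood at 54.5 ± 3.87 against 5906 ± 252 CPM. Of the stress and wound keratins, 4 rose and 0 fell of 4 measured (4 and 0 adjusted over the list alone), with a median log2 fold change of 5.03 (fry adjusted p = 3.67e-04, adjusted p = 0.218 with an estimated correlation). Krt17 rose by 8.67 ± 0.20. Beside both keratinocyte lists, the muscle marker list summed to 1801 ± 122 CPM in tumor sgTgfbr2 against 14596 ± 114 in tumor sgScr, and the gland list to 3727 ± 73.1 against 7.60 to 11.9 in the single tumor sgScr libraries.

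**Figure D2:**
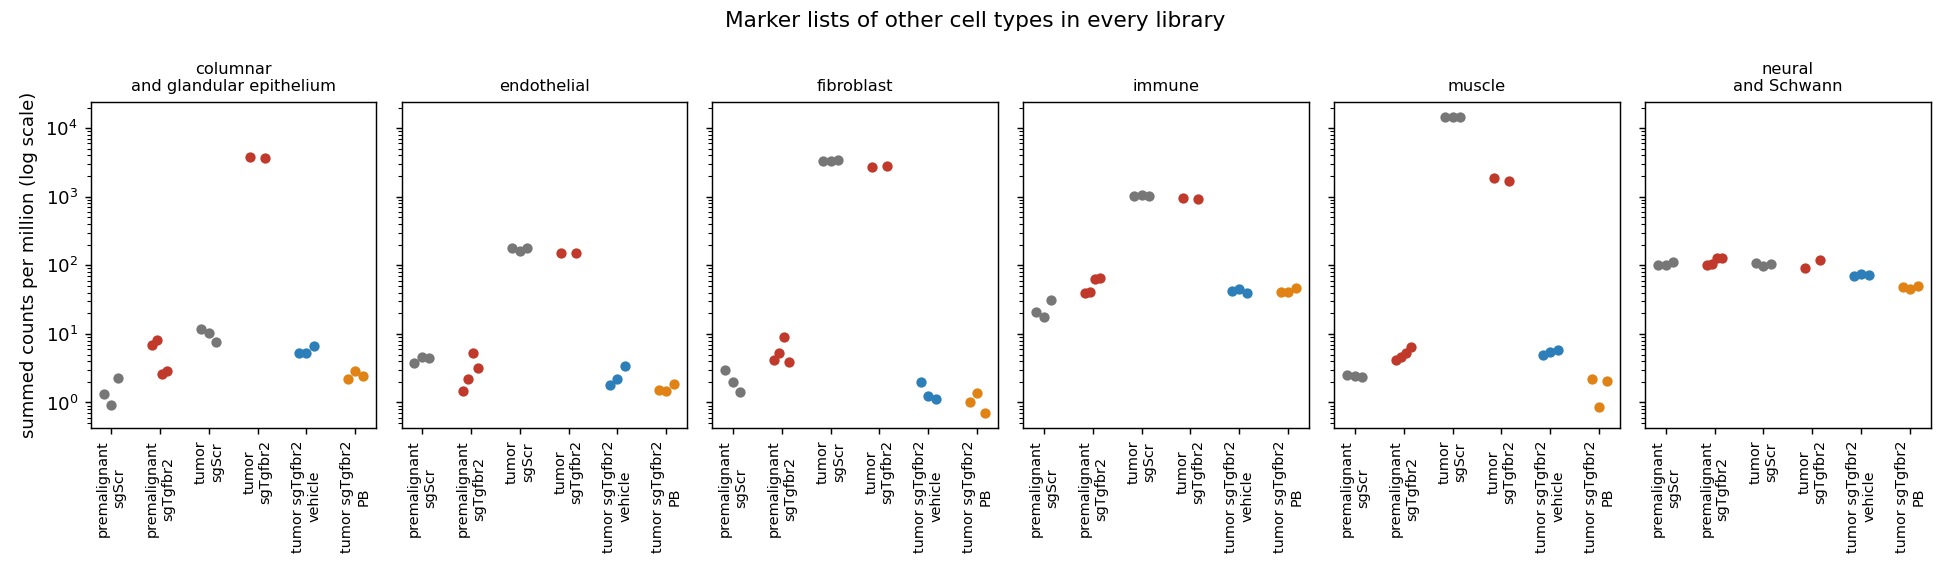
Summed CPM (vertical axis, log scale) of 6 marker lists of other cell types in each of the 18 libraries, 1 point per library. The fibroblast list summed to between 2690 and 3468 in the 5 libraries of the tumor comparison and to at most 8.92 in the other 13.

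The muscle, fibroblast, immune and endothelial marker lists stood higher in these 5 libraries than in the vehicle libraries, which were declared as the same stage and genotype as tumor sgTgfbr2. The immune list summed to 942 to 1044 CPM against 39.6 to 44.7, and the endothelial list to 149 to 181 against 1.82 to 3.37. The columnar and glandular list stood far higher in tumor sgTgfbr2 alone, and the neural list lay closer, at 92.4 to 120.1 CPM in the 5 libraries against 70.6 to 74.3. The muscle list summed to 5.37 ± 0.487 CPM (SD, n = 3) in the vehicle libraries. The fibroblast list summed, in tumor sgScr, tumor sgTgfbr2 and vehicle, to 3362 ± 100.3, 2729 ± 54.8 and 1.45 ± 0.476 CPM, and the columnar and glandular list to a mean of 10.0, 3727 ± 73.1 and 5.78 ± 0.831. The 10 highest genes took 17.3 to 18.4% of counts in tumor sgScr, 9.95 to 10.6% in tumor sgTgfbr2 and 4.44 to 6.10% elsewhere. The tables were deposited and normalized separately, so these levels are set side by side without a test. Within the table, 10 of 11 columnar genes rose and 1 fell (10 and 1 adjusted over the list alone; fry adjusted p = 2.57e-04, adjusted p = 0.172 with an estimated correlation), while the muscle list split into 5 higher and 5 lower (5 and 5 adjusted over the list alone; fry adjusted p = 4.36e-04, adjusted p = 0.257 with an estimated correlation). The 5 higher muscle genes were those of smooth muscle: Acta2 (1.85 ± 0.13), Tagln (1.84 ± 0.13), Cnn1 (1.80 ± 0.14), Myh11 (2.40 ± 0.13) and Actg2 (1.31 ± 0.13), the last 3 named after their values were seen. In CPM of the library total Tagln went from 125 ± 6.08 to 545 ± 59.4 and Myh11 from 30.1 ± 2.84 to 193 ± 0.776.

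Cdkn2a stood at 136 ± 24.3 normalized CPM in tumor sgTgfbr2 and 0.599 ± 0.615 in tumor sgScr (log2 fold change 7.72 ± 0.33, edgeR adjusted p = 5.27e-15). Trp53 was lower (-1.26 ± 0.16, adjusted p = 6.69e-07), and Smad3 (0.30 ± 0.15, adjusted p = 0.084) and Myc (0.40 ± 0.18, adjusted p = 0.0543) did not pass the threshold. Of the TGF-beta and SMAD targets, 17 rose and 6 fell of 29 measured (18 and 7 adjusted over the list alone), with a median log2 fold change of 0.86 (fry adjusted p = 0.00154, adjusted p = 0.379 with an estimated correlation). Members included Thbs1 (2.73 ± 0.12), Ctgf (2.42 ± 0.13) and Pmepa1 (2.39 ± 0.14), with A83-01 listed in the medium. Beside them, the 5 smooth muscle genes rose, and the fibroblast list had 2 higher and 7 lower members of 12 in the same test. The 2, named after their values were seen, were Col1a1 (0.48 ± 0.14) and Col1a2 (0.54 ± 0.13). Of the matrix remodelling genes, 18 rose and 4 fell of 23 measured (18 and 4 adjusted over the list alone) (fry adjusted p = 5.6e-04, adjusted p = 0.257 with an estimated correlation). Members included Tnc (3.53 ± 0.16) and Timp1 (3.36 ± 0.15), beside the same smooth muscle and fibroblast differences. Of 31 lists past the fry threshold, none passed by camera with an estimated correlation (smallest adjusted p = 0.157) and 11 passed with the preset one. Under a replicate block, which left few degrees of freedom for error in these libraries, 25 of the fry calls were lost and 1 reversed. By edgeR, 9095 of 15091 genes passed, 4492 higher and 4603 lower; the authors' deposited table holds 8833. Both groups held these transcripts in each library, so none could be left out for a comparison without them; on the 10903 genes at 1 CPM or more in all libraries of the other tables, an alternative chosen after seeing the data, 6435 passed.

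The sgTgfbr2 effect differed between the stages for 7762 of 15671 genes by edgeR, 3924 with a more positive effect in tumor libraries and 3838 with a more negative one. The ends of that ranking were the gland genes Gkn1, Clps, Pla2g1b, Muc5ac and Chia1, and the cornified envelope or muscle genes Lce3e, Myh8, Lce1f, Lce1a1 and Cox8b, of which the Lce genes and Myh8 belong to multigene families with uncertain counts. Chia1 stood at 1911 CPM in tumor sgTgfbr2 and Cox8b at 92.9 in tumor sgScr. Of the MYC target and ribosome biogenesis genes, 24 of 26 had a more positive effect in tumor libraries (25 adjusted over the list alone; median difference 1.27 log2; fry adjusted p = 1.09e-04, adjusted p = 0.51 with an estimated correlation). Of the squamous differentiation genes, 2 were more positive and 19 more negative of 26 (2 and 19 adjusted over the list alone; adjusted p = 0.0365 with an estimated correlation), and the 4 stress and wound keratins were all more positive (4 adjusted over the list alone; median difference 7.02 log2; fry adjusted p = 8.98e-09, adjusted p = 0.0365 with an estimated correlation), beside the muscle and gland differences above. Cdkn2a (7.49 log2 difference, adjusted p = 1.92e-09), Trp53 (-0.81, 0.00175) and Smad3 (-0.61, 0.01) differed between stages, and for Tgfbr2 (-0.23, 0.352) and Myc (-0.04, 0.948) no difference passed. Stage and deposited table coincide, so the test cannot part them. Of the genes higher in premalignant sgTgfbr2, 1117 were also higher in tumor sgTgfbr2, where independent lists would share 887, and as a set they rose (median log2 fold change 0.19; fry p = 0.00722, p = 0.259 with an estimated correlation). Those lower in premalignant sgTgfbr2 did not pass as a set (fry p = 0.391, p = 0.972 with an estimated correlation). The test and mean pointed down and the median up, and 834 were lower in both where 836 would be shared by independent lists.

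The PB comparison asks what the calcium channel blocker changes in tumor sgTgfbr2 organoids. Genes of the integrated stress response rose. Ddit3, the stress-induced transcription factor CHOP, went from 46.6 ± 1.64 to 449.9 ± 2.91 normalized CPM (SD, n = 3 each; log2 fold change 3.27 ± 0.03). Of the integrated stress response genes, 19 rose and 1 fell of 22 measured (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.84 (fry adjusted p = 7.14e-07, adjusted p = 0.0059 with an estimated correlation). Members included the amino acid transporter genes Slc3a2 (1.57 ± 0.02) and Slc7a5 (1.31 ± 0.02) and Cth (1.88 ± 0.04). Of the unfolded protein response genes, 13 rose and 0 fell of 16 measured (13 and 0 adjusted over the list alone), with a median log2 fold change of 0.83 (fry adjusted p = 1.41e-06, adjusted p = 0.0236 with an estimated correlation). The endoplasmic reticulum chaperone Hspa5 went from 809.8 ± 4.01 to 4152 ± 68.9 CPM. Of the heat shock genes, 10 rose and 2 fell of 12 measured (10 and 2 adjusted over the list alone), with a median log2 fold change of 0.36 (fry adjusted p = 7.52e-07, adjusted p = 0.0236 with an estimated correlation). Members included Hspa1a (2.15 ± 0.03) and Hspa1b (1.97 ± 0.02), near-identical copies whose separate counts are uncertain, and Hsph1 (1.42 ± 0.03).

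Immediate early, hypoxia and interferon genes fell under PB. Of the MAPK feedback and immediate early genes, 5 rose and 17 fell of 22 measured (5 and 17 adjusted over the list alone), with a median log2 fold change of -1.17 (fry adjusted p = 7.52e-07, adjusted p = 0.00591 with an estimated correlation). Dusp6, a feedback phosphatase of ERK, fell from 568 ± 1.37 to 118 ± 2.09 CPM, and Egr1 (-2.03 ± 0.02) and Fosb (-2.22 ± 0.03) fell. Of the hypoxia and glycolysis genes, 3 rose and 18 fell of 22 measured (3 and 19 adjusted over the list alone), with a median log2 fold change of -0.66 (fry adjusted p = 7.14e-07, adjusted p = 0.0059 with an estimated correlation). Members included the prolyl hydroxylase Egln3 (-3.24 ± 0.04), Bnip3 (-2.76 ± 0.05) and the lactate transporter Slc16a3 (-2.40 ± 0.05). Of the interferon response genes, 1 rose and 25 fell of 29 measured (1 and 25 adjusted over the list alone), with a median log2 fold change of -0.46 (fry adjusted p = 7.1e-06, adjusted p = 0.0371 with an estimated correlation). Members included Isg15 (-1.12 ± 0.06) and Usp18 (-1.18 ± 0.06). Of the proliferation genes, 3 rose and 25 fell of 35 measured (3 and 25 adjusted over the list alone), with a median log2 fold change of -0.32 (fry adjusted p = 1.41e-06, adjusted p = 0.0319 with an estimated correlation). Members included Rrm2 (-1.19 ± 0.05) and Mcm7 (-0.87 ± 0.04).

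Cholesterol synthesis and lysosome genes rose. Of the former, 20 rose and 2 fell of 25 measured (20 and 2 adjusted over the list alone), with a median log2 fold change of 0.33 (fry adjusted p = 2.45e-06, adjusted p = 0.0371 with an estimated correlation). Members included lanosterol synthase Lss (1.13 ± 0.03) and Insig1 (1.02 ± 0.03). Of the lysosome and autophagy genes, 20 rose and 1 fell of 25 measured (20 and 1 adjusted over the list alone), with a median log2 fold change of 0.26 (fry adjusted p = 1.41e-06, adjusted p = 0.0371 with an estimated correlation). Members included Sqstm1 (1.09 ± 0.03) and Neu1 (1.34 ± 0.06). Of the calcium channel and handling genes, 7 rose and 5 fell of 24 measured (7 and 5 adjusted over the list alone) (fry adjusted p = 1.72e-04, adjusted p = 0.687 with an estimated correlation). The list's test and mean pointed up and its median down. The plasma membrane calcium pump Atp2b1 rose by 1.09 ± 0.02 and the reticulum pump Atp2a2 by 0.42 ± 0.02.

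The TGF-beta and SMAD targets split under PB: 10 rose and 10 fell of 25 measured (10 and 10 adjusted over the list alone), with a median log2 fold change of -0.11 (fry adjusted p = 0.00576, adjusted p = 0.687 with an estimated correlation). Of all 12801 genes, 4666 passed as higher and 4713 as lower, so such a split is not particular to these targets. Junb (-0.86 ± 0.03) and Bhlhe40 (-0.89 ± 0.03) fell, while Snai2 (1.13 ± 0.04) and Ski (0.52 ± 0.03) rose. Smad3 was higher under PB, at 160.3 ± 4.22 against 119.8 ± 0.763 CPM (log2 fold change 0.42 ± 0.03, edgeR adjusted p = 1.71e-19). Tgfbr2 (-0.36 ± 0.04) and Trp53 (-1.05 ± 0.05) were lower, Cdkn2a was higher (0.34 ± 0.03) and Myc was slightly lower (-0.09 ± 0.02). RNA counts do not measure Smad3 phosphorylation, and A83-01 was listed in the medium of these libraries too. Of 29 lists past the fry threshold, 9 passed by camera with an estimated correlation: integrated stress response, unfolded protein response, heat shock, immediate early, hypoxia, interferon, proliferation, cholesterol and lysosome. With the preset correlation 10 passed.

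**Figure D3:**
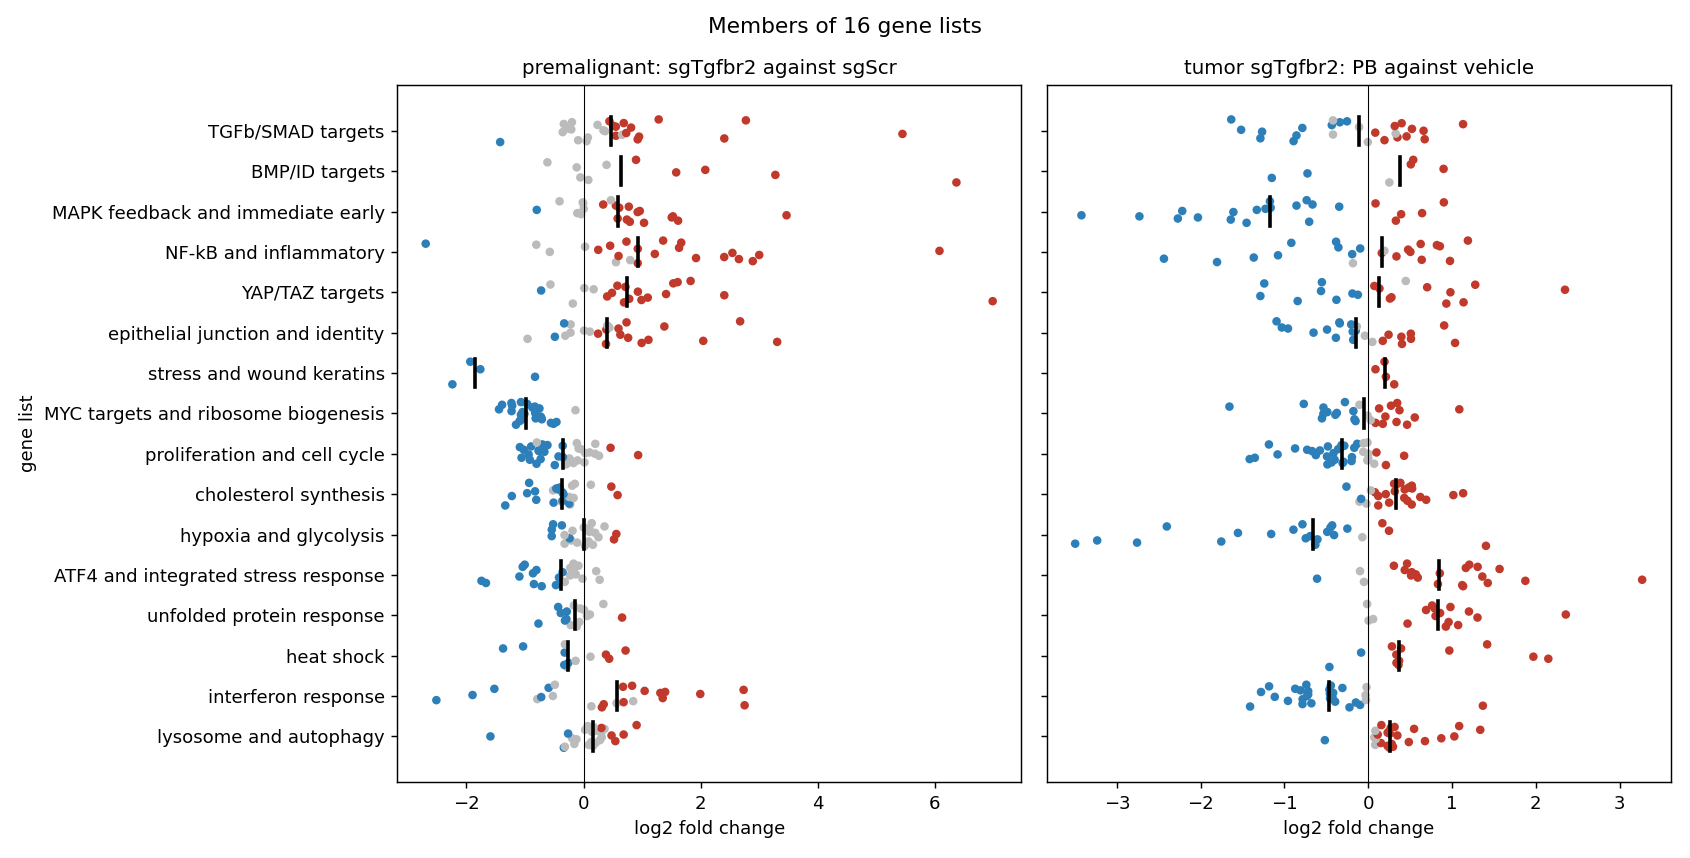
Fitted log2 fold changes (horizontal axis) of the members of 16 gene lists in 2 comparisons, red and blue for members higher or lower past an adjusted p of 0.05, grey for the rest, with a black bar at each list's median. The integrated stress response list has a median of -0.39 in premalignant sgTgfbr2 against sgScr and 0.84 in PB against vehicle.

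Among the single genes taken by the rule, besides Ddit3, the highest log2 fold changes under PB belonged to the histone genes Hist3h2a (3.39 ± 0.08) and Hist3h2ba (3.32 ± 0.13) and to H2-K2 (3.02 ± 0.08), all of multigene families with uncertain counts, and to Acot2 (2.99 ± 0.15), Fam171b (2.88 ± 0.14), the circadian repressor Nfil3 (2.68 ± 0.05) and Tmem74 (2.68 ± 0.18). The lowest were Islr (-4.56 ± 0.20), Ndufa4l2 (-3.92 ± 0.09), the beta-arrestin Arrb1 (-3.89 ± 0.17), Homez (-3.66 ± 0.19), Ppp1r10 (-3.53 ± 0.05), Egr3 (-3.42 ± 0.07), Egln3 and Nlrp10 (-3.19 ± 0.14); Egr3 and Egln3 are also members of the immediate early and hypoxia lists. By edgeR, 9379 of 12801 genes passed, 4666 higher and 4713 lower; the authors' deposited table holds 8434. Replicates lay close to counting noise (chi-square per degree of freedom 1.51 to 2.03), and with an absolute log2 fold change of at least 1 there were 510 higher and 1087 lower genes.

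The genes changed in tumor sgTgfbr2 were followed under PB to ask whether they moved the other way. Those higher in tumor sgTgfbr2 had a median log2 fold change of 0.05 under PB (fry p = 5.07e-07, p = 0.00585 with an estimated correlation, p = 0.170 with a preset one; the mean, -0.02, pointed down), and those lower had a median of -0.08 (fry p = 2.13e-04, p = 0.00674 and p = 0.221). The higher sets shared 1637 genes where independent lists would share 1409.8, and the lower sets 1371 against 1244. With sets of an absolute log2 fold change of at least 1, an alternative set beforehand, the 1909 higher genes had a median of -0.01 and a mean of -0.10 under PB, while fry pointed up (p = 1.498e-04, p = 0.884 with an estimated correlation, p = 0.942 with a preset one), and they shared 695 genes with the higher PB genes against 698. The 1761 lower genes had a median of -0.19 (fry p = 2.18e-07, p = 9.21e-04 with an estimated correlation, p = 0.0287 with a preset one) and shared 792 against 654. Across genes, which are not independent replicates, Pearson's r was 0.0623 and Spearman's rho 0.0982. The sets come from tumor groups that also differed in other RNA. In tumor sgTgfbr2 against tumor sgScr the gland list summed to 3727 against 10.0 CPM and the muscle list to 1801 against 14596. The sets therefore cannot part an effect of the guide from RNA of other cell types.

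The 2 premalignant sgTgfbr2 lines differed from each other in 3535 of 13438 genes by edgeR, 1768 higher and 1767 lower in line 2. Spp1, the secreted phosphoprotein osteopontin, stood at 1027 ± 48.1 CPM in line 1 and 63.6 ± 0.284 in line 2 (SD, n = 2 each). Mtus2 (-4.05 ± 0.24), Lypd2 (-3.87 ± 0.27) and Sprr2d (-3.44 ± 0.19), among the strongest rises over sgScr, were also lower in line 2. Rhox4a, of a family with near-identical copies and so of uncertain counts, stood at 18.8 CPM in line 1 with no count in line 2. The transcription factor Sim2 (6.27 ± 0.24), Wnt5a (3.73 ± 0.19), Rab6b (3.69 ± 0.22) and Tenm3 (3.67 ± 0.23) were higher in line 2. Sim2 stood at 0.456 normalized CPM in line 1, 34.8 in line 2 and 46.9 in sgScr, and Tenm3 at 1.44, 18.3 and 24.9. Wnt5a stood at 1.70, 22.5 and 11.7, and Rab6b at 2.40, 30.7 and 12.2. By mean level, all of them were lower in line 1 than in sgScr, and Sim2 and Tenm3 did not exceed sgScr in line 2. Of 24 NF-kB and inflammatory genes, 17 were lower in line 2 and 0 higher (18 and 0 adjusted over the list alone; median log2 fold change -0.89; fry adjusted p = 0.00309, adjusted p = 0.249 with an estimated correlation). Leaving out sgTgfbr2 replicate 1, 2, 3 or 4 lowered the number of genes higher in line 2 to 691, 931, 792 or 1004, with the lone sample of its line assumed to vary like the other groups.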

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

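The tests of RNA from other cell types, of an exchange of single libraries, of loss of Tgfbr2 alone, of a few strongly changed genes and of a length trend, and the splits with lines kept whole, were chosen only after the results were seen.

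Genes of muscle, connective tissue or gastric glands were abundant in the 5 libraries of the tumor sgTgfbr2 against sgScr comparison, where mean Myc was 44.7 and 72.5 CPM against 349 to 518 in the other 4 groups. An exchange of single libraries between the 2 groups is argued against by 0 of 5 libraries correlating best with the other group (within groups at least 0.976, between groups at most 0.704), while an exchange of the 2 groups as a whole was not tested, with Tgfbr2 running the way of the labels at 67.5 and 71.2 CPM in tumor sgTgfbr2 against 112 to 129 in tumor sgScr. Loss of Tgfbr2 alone is argued against by the vehicle libraries, of the same declared stage and genotype, whose highest sum of the columnar and glandular list was 6.74 CPM, against a lowest sum of 3676 in tumor sgTgfbr2. RNA of other cell types in both groups stays open as a candidate source, because the fibroblast list summed to at least 2690 CPM in each of the 5 libraries, with 10 or 11 of its 12 members at 10 CPM or more, and to at most 8.92 CPM in the other 13, with 0 such members. Its most abundant genes were Dcn in tumor sgScr (1255 ± 163 CPM) and Col3a1 in tumor sgTgfbr2 (881 ± 15.0 CPM), no sort is given in the labels, and neither tissue in place of cultured organoids nor a difference in tumors or animals between the tables was tested.

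Chromosome 5 genes were lower in line 2 than in line 1 of premalignant sgTgfbr2, by a median of -0.43 log2 relative to the other autosomes over 629 genes at 8 CPM or more. Transcript length and GC content are argued against, because the difference was -0.44 after correction for both. A median is little moved by a few strongly changed genes, so the test of them was largely settled in advance by the shift. By that test 92.5% of the chromosome's genes lay below the other autosomes' median. Each of 10 parts of the chromosome, of about equal gene number, had a median below it, which is consistent with a change in copy number of chromosome 5, a hypothesis that RNA counts cannot settle. Relative to the other autosomes and sgScr, the chromosome's median was 0.47 in line 1 and 0.03 in line 2, and other differences between the lines were not tested.

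MYC target and ribosome biogenesis genes were lower in premalignant sgTgfbr2, with a median of -0.99 log2 over 26 genes. The list did not pass by camera with an estimated correlation (adjusted p = 0.337). A trend in transcript length is argued against, because the median was -0.92 after correction for length and GC content, and 1 of the 2 lines alone is argued against, because the list's median was -0.89 in the line where it fell less and -1.05 in the other. An effect of the sgTgfbr2 guide and a difference in culture stay open as untested hypotheses.

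For the premalignant comparison, 1 of 7 splits that keep each sgTgfbr2 line whole gave as many genes, too few splits for a share under 0.05; the real split gave 6057 and the highest other 0 by edgeR (1393 at an unadjusted p under 0.05). Of the 35 splits of single libraries, which treat the 2 libraries of a line as independent, 1 gave as many and the highest other 0 by edgeR (4686 unadjusted). For PB, 1 of 10 splits gave as many genes, too few splits for a share under 0.05; the real split gave 9379 and the highest other 0 by edgeR (43 unadjusted).

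Among premalignant sgTgfbr2 libraries, 8 of 134 measures tested (133 named genes and the library total) had 1 library far from the other 3, where chance gives about 1 in 20. Those reported here were, in normalized CPM, Cdkn2b in replicate 1 (54.7), Tnfrsf19 in replicate 2 (0.0583), and in replicate 3 Bmp4 (2.15), Egr1 (798), Lama5 (811), Tpi1 (911) and Npc2 (139).

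For 7762 genes the difference of sgTgfbr2 from sgScr was unlike in the tumor and premalignant libraries, by the edgeR interaction test. Stage and deposited table coincide, and the tumor libraries held the muscle and gland RNA described above. The test therefore cannot assign the difference to stage or to the guide. Adjusted p-values were 0.01004 for Smad3, 0.00175 for Trp53 and 1.92e-09 for Cdkn2a. For the genes at the upper end they were 1.19e-05 for Gkn1, 3.33e-04 for Clps, 3.31e-05 for Pla2g1b, 2.21e-05 for Muc5ac and 4.03e-06 for Chia1. For the lower end they were 1.1e-05 for Lce3e, 6.78e-05 for Myh8, 7.9e-07 for Lce1f, 1.01e-04 for Lce1a1 and 4.99e-05 for Cox8b.

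Between the 2 premalignant sgTgfbr2 lines 3535 genes differed by edgeR. Adjusted p-values were 7.12e-10 for Sim2, 9.11e-09 for Wnt5a, 4.93e-08 for Rab6b and 6.11e-08 for Tenm3, all higher in line 2. They were 1.4e-08 for Rhox4a, 4.02e-08 for Mtus2, 4.39e-12 for Spp1, 2.62e-07 for Lypd2 and 1.66e-08 for Sprr2d, all lower in line 2.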

How the results depend on the processing

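The restriction of the tumor and stage fits to genes at 1 CPM or more in the other libraries, the premalignant fit without chromosomes 1, 5, 14 and Y, the leave-one-out of the line contrast, the list tests of each line against sgScr and the premalignant sets under PB were chosen only after the results were seen. Counts of genes past the threshold, in each direction, stayed within 1.5 times under the DESeq2, limma-voom, filter, line, gene restriction and block alternatives run. The 1-mean-per-line fit called all 6057 premalignant genes among its 8122. That fit leaves the spread between the lines out of its error, so the overlap is no check of the 6057. A minimum absolute log2 fold change of 1 left 1102 higher and 437 lower genes in the premalignant comparison, 2499 and 2927 in the tumor comparison and 510 and 1087 under PB, fewer by construction. With each replicate left out, the counts ranged from 1954 to 3018 higher and 2089 to 2979 lower in the premalignant comparison (1977 and 1954 higher without sgScr replicate 1 or 2, the cause was not tested), 3960 to 4335 and 4054 to 4382 in the tumor comparison, 4501 to 4552 and 4518 to 4564 under PB, and 3479 to 3911 and 3382 to 3803 in the stage contrast. In the line contrast they ranged from 691 to 2519 higher and 757 to 2528 lower, the counts without sgTgfbr2 replicate 1, 2, 3 or 4 being 691, 931, 792 and 1004 higher and 757, 1003, 763 and 964 lower; a lone sample left in a line is assumed to vary like the other groups. Replicate numbers did not pair the samples (correlations of deviations -0.104 to 0.142 premalignant, -0.0871 to -0.0172 tumor, -0.0095 to 0.0061 PB). A replicate block gave 2260 higher and 2479 lower genes, 3739 and 3868, and 4670 and 4695. Under the block 5, 25 and 1 list calls were lost and the mesenchymal list in the tumor comparison reversed (fry adjusted p = 0.689). In the tumor comparison the block left few degrees of freedom for error, so losses there are no sign of pairing. The cause was not tested further. With each line against sgScr, 3 premalignant list calls were lost in line 1 (unfolded protein response, fry adjusted p = 0.147, oxidative phosphorylation, 0.121, and heat shock, 0.0688) and 2 in line 2 (matrix remodelling, 0.0836, and heat shock, 0.134), with fewer libraries by construction, and 3 and 4 were gained. The squamous list, without a call over both lines, passed downward in line 1 (fry adjusted p = 0.0365) and upward in line 2 (fry adjusted p = 0.0215), and the cause was not tested. For sets of genes, the p of the sgTgfbr2-changed sets under PB rose to 0.170 and 0.221 with a preset correlation (0.942 and 0.0287 for sets of an absolute log2 fold change of at least 1, the higher one at p = 0.884 with an estimated one), and that of the premalignant-higher set in the tumor comparison to 0.259 with an estimated one. The premalignant-higher set under PB (fry p = 0.00126, up, with a median and mean below 0) turned down at p = 0.704 with a preset and p = 0.373 with an estimated correlation. The lower set (fry p = 1.25e-05) lost its call at p = 0.499 with the preset and p = 0.142 with the estimated correlation. Camera compares a set with other genes and fry does not, and the cause was not tested further. No named gene reversed under any alternative run. Apart from Tgfbr2, Smad3, Trp53, Cdkn2a and Myc, the named genes were chosen by their results in these libraries. Their stability is therefore no independent check. Calls were lost in 34 of 2127 premalignant, 10 of 1726 tumor, 6 of 140 stage, 0 of 70 line and 0 of 1631 PB values, each a named gene under 1 alternative, and gained in 11 premalignant and 3 tumor values. A pseudocount alternative did not apply to counts, so it has no value.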

Other observations

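The list medians of single lines given here, the values of chromosomes 1, 14 and Y and the count without them were chosen only after the results were seen. Other gene groups changed in each comparison. In premalignant sgTgfbr2, of the MHC class I genes, which present peptides to T cells, 8 rose and 0 fell of 11 measured (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.41 (fry adjusted p = 0.0167, adjusted p = 0.404 with an estimated correlation). Members included Psmb8 (1.12 ± 0.17) and Tapbp (0.51 ± 0.13), and the list's median was 0.36 in line 1 and 0.23 in line 2. Of the nuclear oxidative phosphorylation genes, 2 rose and 15 fell of 26 measured (2 and 20 adjusted over the list alone), with a median log2 fold change of -0.36 (fry adjusted p = 0.0383, adjusted p = 0.601 with an estimated correlation). Members included Ndufs1 (-0.88 ± 0.11) and Uqcrc1 (-0.54 ± 0.10), which fell, and Sdhc (0.55 ± 0.09), which rose. The list's median was -0.21 in line 1, where it did not pass by fry (adjusted p = 0.121), and -0.46 in line 2. Of the interferon response genes, 12 rose and 5 fell of 23 measured (13 and 5 adjusted over the list alone), with a median log2 fold change of 0.56 (fry adjusted p = 0.0232, adjusted p = 0.601 with an estimated correlation). Members included Cxcl10 (2.75 ± 0.23) and Irf7 (1.35 ± 0.18), which rose, and Ifit2 (-2.51 ± 0.21), which fell. Beside the MHC class I and interferon genes, the immune marker list summed to 52.0 ± 13.5 CPM against 23.3 ± 6.99 in sgScr. In the tumor comparison, of the BMP and ID targets, 8 rose and 0 fell of 9 measured (8 and 0 adjusted over the list alone), with a median log2 fold change of 1.82 (fry adjusted p = 5.6e-04, adjusted p = 0.355 with an estimated correlation). Members included Id2 (3.19 ± 0.16) and Bambi (2.83 ± 0.27), beside the smooth muscle gene Acta2 (1.85 ± 0.13) and the gland list. The simple keratins Krt8 (8.37 ± 0.18) and Krt18 (8.01 ± 0.18) were higher, beside the gland list that summed to 3727 ± 73.1 CPM against 7.60 to 11.9 in the single tumor sgScr libraries.

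Under PB, of the p53 targets, 11 rose and 4 fell of 17 measured (11 and 4 adjusted over the list alone), with a median log2 fold change of 0.26 (fry adjusted p = 1.55e-05, adjusted p = 0.214 with an estimated correlation). Members included the proapoptotic gene Bbc3 (2.58 ± 0.09) and Eda2r (2.46 ± 0.09), which rose, and Btg2 (-0.61 ± 0.03), which fell, in organoids declared Trp53-null. Of the squamous differentiation genes, 5 rose and 11 fell of 23 measured (5 and 11 adjusted over the list alone), with a median log2 fold change of -0.25 (fry adjusted p = 9.77e-06, adjusted p = 0.0606 with an estimated correlation). Members included the suprabasal keratins Krt4 (-1.80 ± 0.03) and Krt13 (-0.83 ± 0.02). The chemokine genes Cxcl1 (-2.44 ± 0.05) and Ccl2 (-1.80 ± 0.10) were lower.

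Chromosome 1 genes had a median of 0.30 log2 in line 1 and 0.33 in line 2 against sgScr, relative to the other autosomes, over 539 genes at 8 CPM or more, and chromosome 14 genes 0.18 in line 2 and -0.04 in line 1. The Y genes Ddx3y, Eif2s3y, Kdm5d and Uty had a median of -1.60 in line 2 and -0.03 in line 1 by the same measure. Without genes of chromosomes 1, 5, 14 and Y, 5099 of 11116 genes passed in the premalignant comparison.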
